A study of Mus musculus with 4 samples.

How the data were processed

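RNA was extracted with Trizol and libraries were made with the NEBNext Ultra Directional kit, per the labels' protocols, from 4 samples: 2 WT and 2 Elovl6 KO. The groups and replicate numbers came from the sample titles. The submitters' processing notes name the mouse build mm10, and the aligner, the counter, their versions and the use of strand are not given in the sources used here. The kit keeps strand, but without a statement on counting, reads of overlapping genes on opposite strands cannot be told apart.

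The deposited table holds whole-number counts per gene for 51826 features, with separate columns per sample for uniquely placed exon reads, total exon reads, uniquely placed intron reads and uniquely placed gene reads, per the file headers. The authors' main values are counts that lie between the unique and the total exon reads, so they include a part of the multi-mapping reads, and 96.0% to 96.2% of them were uniquely placed. Of the features, 18706 have an exon length of 0 and can hold no exon counts. The authors' own test in the deposited table is an EDGE test of WT against KO with tagwise dispersions, per the file headers, and gives a p-value, a corrected p-value and a signed fold change per feature. Of the deposited features, 888 had a corrected p under 0.05, 569 positive and 319 negative. Of the 329 genes called here, 313 were among them, all in the same direction. Gene starts are counted from 0 in the deposited table and are given here counted from 1. GENCODE vM21 of the same build held 99.6% of the gene IDs, and biotype, strand and overlapping genes were taken from it by ID.

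Gene counts summed to 9883596 and 11941588 in WT and 8986502 and 9699502 in KO. A count of 10 has a counting error of 31.6% and a count of 100 one of 10.0%, and 3 counts equal 0.251 to 0.334 CPM in these libraries. Intervals of count ratios are exact (Clopper-Pearson, from the binomial share of the counts in each group), and intervals and floors cover counting error only, since the reads carry no molecular identifiers. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 4.45 between the WT and 6.56 between the KO libraries, so none was treated as a repeat of another. The first principal component of log2 CPM held 70.4% of the variance and separated the genotypes.

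Genes were filtered with filterByExpr (minimum count 10, minimum total 15), scaled by TMM (factors 0.995 to 1.00) and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment over 11738 genes and no replicate block. Means and SDs in CPM use TMM-scaled library sizes, except for the plot of Elovl6 and its intron reads, scaled by gene counts alone. Gene lists were tested with camera (preset correlation 0.01, two-sided, at least 5 measured members, adjusted over 33 lists) in limma 3.58.1, with an estimated correlation and fry beside it. In all 36 lists of lipid, leukaemia, myeloid, other cell type, signalling, stress, proliferation, metabolism and quality genes were used, and Elovl6 is in none. The main test, the lists and the rule for naming genes were fixed before the data were examined. A sex-linked list served only to look at the libraries. The alternatives were RLE and upper quartile scaling, DESeq2 1.42.0, limma-voom, other filters and thresholds, a replicate block, each library left out, abundant genes left out, and uniquely placed exon reads, the last chosen after the data were seen. Tables were handled with pandas 2.3.3 in Python 3.11.15.

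The genes named follow that rule. It takes Elovl6; among genes past an adjusted p of 0.05, with both KO libraries on one side of both WT libraries and a mean of at least 1 CPM, the 12 largest rises and 12 largest falls; and up to 4 members of each list with the smallest p. Predicted and clone-named genes of listed name types are not named, which left out 6 higher and 12 lower genes. Genes named outside the rule are said to be, and a few genes and 1 list that it covers are not reported here.

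The test was tried on counts simulated for this comparison, with the real means, library sizes and gene-wise dispersions, about 11594 genes and 200 changed genes in each of 10 draws. It recovered 53.7% of genes changed 1.5-fold, 76.9% of those changed 2-fold and 94.8% of those changed 4-fold. Of its calls 10.7% were genes left unchanged, above the nominal 5%, so the adjusted p of single genes near 0.05 is optimistic. A list of 25 genes raised 1.3-fold had an unadjusted camera p under 0.05 in 10 of 10 draws with either correlation. An unchanged list did so in 0 of 10. The simulated genes were independent of each other, unlike real ones. The real lists were called at an adjusted p, a stricter bar. Most called lists also had medians nearer to no change than 1.3-fold, so these draws do not show whether such lists would be found.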

Results

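Elovl6 encodes an enzyme of the endoplasmic reticulum that lengthens palmitate to stearate, and MLL-AF9 is a fusion oncoprotein that drives acute myeloid leukaemia. The series measured what loss of Elovl6 does to gene expression in mouse bone marrow cells transformed by MLL-AF9. Lineage-negative, c-kit positive marrow cells, a fraction enriched for stem and progenitor cells, carried MLL-AF9 and were sampled at a point labelled week 2. Total RNA was sequenced from 2 wild-type (WT) and 2 Elovl6 knockout (KO) samples. The WT libraries held 9883596 and 11941588 gene counts, and the KO libraries held 8986502 and 9699502. Nothing in the labels says that the replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

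Spliced Elovl6 RNA was nearly lost from the libraries labelled KO. Elovl6 (ENSMUSG00000041220) lies on the plus strand of chromosome 3 at 129532355 to 129638495 in mm10 and has 6431 bases of exon. Its gene counts were 1290 and 1673 in WT and 17 and 34 in KO. Scaled by library size, the level was 135.8 ± 6.23 CPM (counts scaled to a common library size; SD, n = 2) in WT and 2.70 ± 1.14 (SD, n = 2) in KO, a 49.7-fold lower level. The log2 fold change was -5.63 (SE 0.17), with an adjusted p of 4.52e-05 in edgeR's quasi-likelihood test. The fold change in the authors' deposited table was -50.08. Reads in the introns of Elovl6 were reduced far less, from 280.5 ± 15.3 (SD, n = 2; scaled like CPM by the library's gene counts) in WT to 145.5 ± 21.3 (SD, n = 2) in KO. The intron log2 fold change was -0.996 (SE 0.093), with an adjusted p of 0.00122 in the same test. Relative to the WT mean, KO replicate 1 kept 1.40% of the gene counts and 46.5% of the intron reads, and KO replicate 2 kept 2.59% and 57.2%. An unnamed predicted gene overlaps Elovl6 on the opposite strand, and whether counting used the strand is not given in the sources used here.

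**Figure D1:**
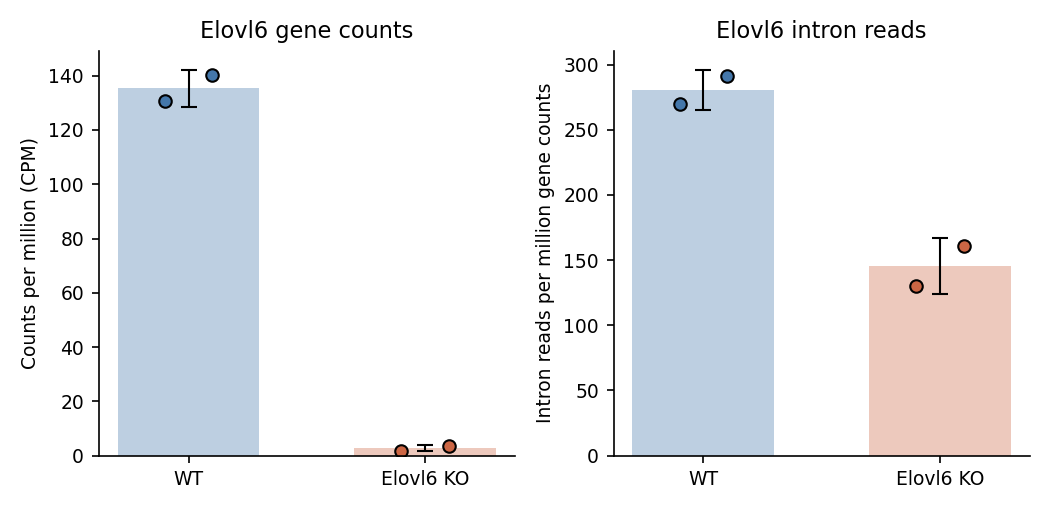
Elovl6 in each library (points), with group means (bars) and SD (n = 2): left, gene counts in CPM; right, uniquely placed intron reads scaled by gene counts in the same way. Gene counts fell from a mean of 135.3 to 2.70 CPM, while intron reads went from 280.5 to 145.5.

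The comparison of KO with WT asks which other genes change with Elovl6. Lysozyme 2 (Lyz2) rose from 132 to 598 CPM (log2 fold change 2.18, SE 0.22). Lipoprotein lipase (Lpl), which frees fatty acids from circulating triglyceride, rose from 12.4 to 59.6 CPM (2.26, SE 0.33), and Cybb, the catalytic subunit of the phagocyte NADPH oxidase, rose from 29.6 to 116 CPM (1.96, SE 0.20). Genes lower in KO included Car2, a carbonic anhydrase (log2 fold change -1.85, SE 0.27), and H2-DMb1, which helps load peptide on class II molecules (-2.18, SE 0.23). In all, 329 of 11738 genes tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 214 higher and 115 lower, with a median absolute log2 fold change of 1.03. In all 329 both KO libraries lay on one side of both WT libraries. A call with 2 against 2 libraries largely brings this with it, so it adds no support. It held for 53.8% of tested genes against 33.3% by chance, but genes do not vary independently of each other. The number of calls varied widely with the library left out. Such a fit has fewer samples and assumes that the lone sample varies like the other group. A lower number there need not mean that the calls rest on a single library. Far more genes passed without KO replicate 1 than with all 4 libraries. A gene below that passed only with a library left out is therefore not better supported by it. The number was also 1677 with no filter on low counts, 112 with a mean of at least 10 CPM and 875 with the replicate number as a block.

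**Figure D2:**
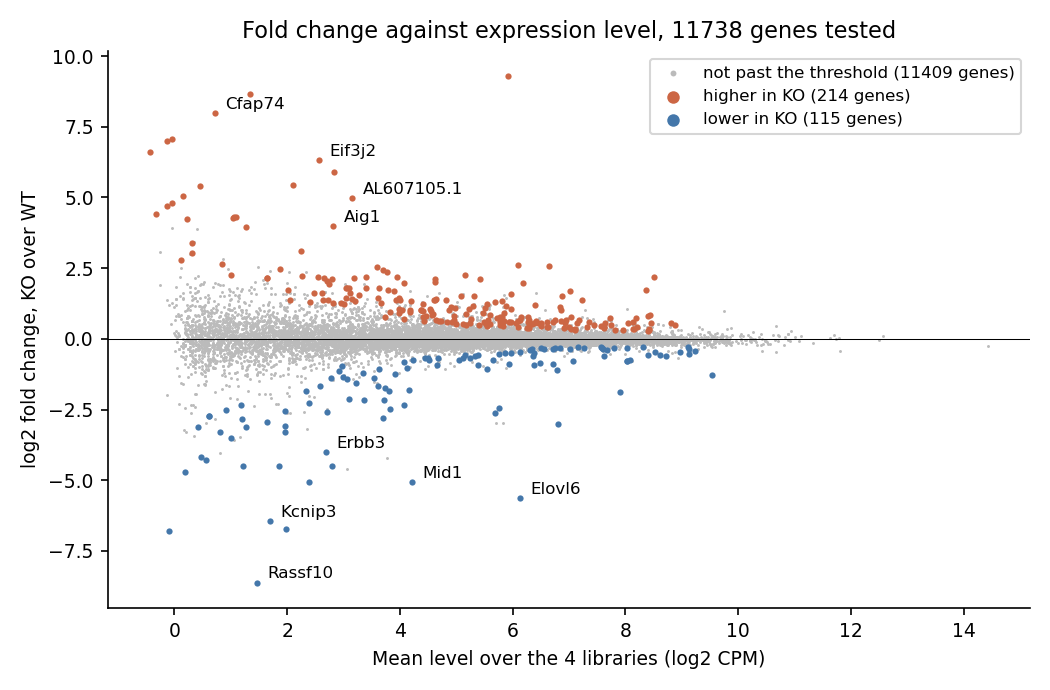
Log2 fold change of KO over WT against the mean level in log2 CPM for the 11738 genes tested. The 214 genes higher in KO and the 115 lower (adjusted p under 0.05) are coloured, and the genes with the largest changes are at near-absent levels in one genotype.

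The genes with the largest rises were nearly silent in WT. Eif3j2 (ENSMUSG00000043424, chromosome 18, 43475418 to 43477796), a copy of the translation initiation factor gene Eif3j1, had 3 counts in all in WT and 108 and 116 in KO, a ratio of 86.8 (exact 95% counting interval 29.3 to 424.2). Eif3j1, named here after its values were seen, moved the other way, with a log2 fold change of -2.33 (SE 0.16). Cfap74, a gene of motile cilia, had no counts in WT and 27 and 31 in KO, at least 22.5-fold higher against a floor of 3 counts over the group. The RNA-binding protein gene Msi1 had 1 count in WT and 23 in each KO library, a ratio of 53.5 (interval 9.13 to 2158), and the lectin gene Clec2g had a ratio of 21.5 (interval 5.55 to 184.2). AL607105.1, a clone-named protein-coding gene, rose from 0.566 ± 0.208 to 17.7 ± 1.04 CPM (SD, n = 2 each; log2 fold change 4.97, SE 0.28, edgeR adjusted p = 0.000623). Aig1, a hydrolase of fatty acid esters, rose with 3.995 (SE 0.43), as did Apbb1 (4.32), Rnase2a (4.29), H2-Q10 (3.95), Arhgef37 (3.38) and Plxdc2 (3.12). Uniquely placed reads were 4.25%, 21.7% and 43.1% of the exon reads of Eif3j2, AL607105.1 and H2-Q10, and made up all counts of the first 2 and 74.2% of those of H2-Q10. The size for Eif3j2 rests on 3 counts in WT replicate 1 and none in WT replicate 2.

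The largest falls besides that of Elovl6 were as steep. Rassf10 (chromosome 7, 112953962 to 112957457), of the Ras-association family, had 50 and 55 counts in WT and none in KO, at least 30.1-fold lower. The proteasome subunit gene Psma8 had 36 and 119 counts in WT and 1 in KO, a ratio of 133.3 (95% counting interval 23.6 to 5298). Kcnip3, a calcium-binding protein gene, had 54 and 70 counts against 1, a ratio of 106.6 (interval 18.8 to 4245). Mid1, a ubiquitin ligase gene on chromosome X, fell from 34.6 ± 5.93 to 1.03 ± 0.434 CPM (SD, n = 2 each; log2 fold change -5.07, SE 0.27, edgeR adjusted p = 0.000623). Erbb3, a receptor for neuregulin, fell from 11.3 to 0.715 CPM (log2 fold change -3.997, SE 0.47). Pcdh11x and Boc were lower at ratios of 21.5 (interval 5.65 to 182.4) and 19.8 (interval 5.17 to 168.2), and Prps1l1 and Fam135b had log2 fold changes of -3.30 and -3.12. Erdr1 (-5.06) and Xlr4b (-4.48) also fell, with 15.4% and 28.9% of exon reads uniquely placed. KO counts were 5 and 0 for Xlr4b and 2 and 0 for Boc, so those sizes rest on KO replicate 1. Of the genes of largest change named here, Elovl6, Eif3j2, AL607105.1, Aig1 and Mid1 stayed past the threshold in every alternative that tested them; the others lost it in at least 2. Of the 52 called genes that the naming rule gave and that are reported here besides Elovl6, 48 lost the call without WT replicate 1 and 47 without WT replicate 2.

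Myeloid lists moved in different directions. Of 24 measured monocyte and macrophage genes, Cybb and Lgals3 (log2 fold change 1.497, SE 0.24) rose and none fell; 15 were higher and 1 lower when adjusted over the list alone. The list median was 0.83, and camera placed it above other genes (adjusted p = 3.31e-08). Ctss and Klf4 had log2 fold changes of 1.11 and 1.71 and missed the threshold (adjusted p = 0.0507 and 0.0648, edgeR); both passed without KO replicate 1 (1.43 and 2.16) and without KO replicate 2 (0.70 and 1.02). Of 16 primary granule genes none passed the test over all genes or over the list alone, and the median was -0.38 (camera adjusted p = 0.00157). Elane and Prtn3, proteases of that granule, had values of 1895 and 1570 CPM in WT and 1366 and 1160 in KO. Their log2 fold changes of -0.47 and -0.44 were -0.25 and -0.23 without KO replicate 2, and -0.74 and -0.68, past the threshold, without KO replicate 1. Of 9 eosinophil genes none passed over all genes and 5 were lower over the list alone; the median was -2.63 (camera adjusted p = 5.9e-05). Prg2 and Epx, granule proteins of eosinophils, had log2 fold changes of -2.97 (SE 0.72) and -2.97 (SE 0.78), and missed the threshold; these were -1.78 and -1.53 without WT replicate 1, and both passed without KO replicate 1 (-4.29 and -4.15). Other lists hold 3 of the monocyte, 3 of the primary granule and 2 of the eosinophil genes. With an estimated correlation these 3 lists had adjusted p = 0.547, 0.638 and 0.547, so no call held. Single libraries set the sizes: without KO replicate 2 the monocyte median was 0.33 and the primary granule median -0.10 (adjusted p = 0.0503), without KO replicate 1 the latter was -0.71, and without WT replicate 1 the eosinophil median was -1.12.

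**Figure D3:**
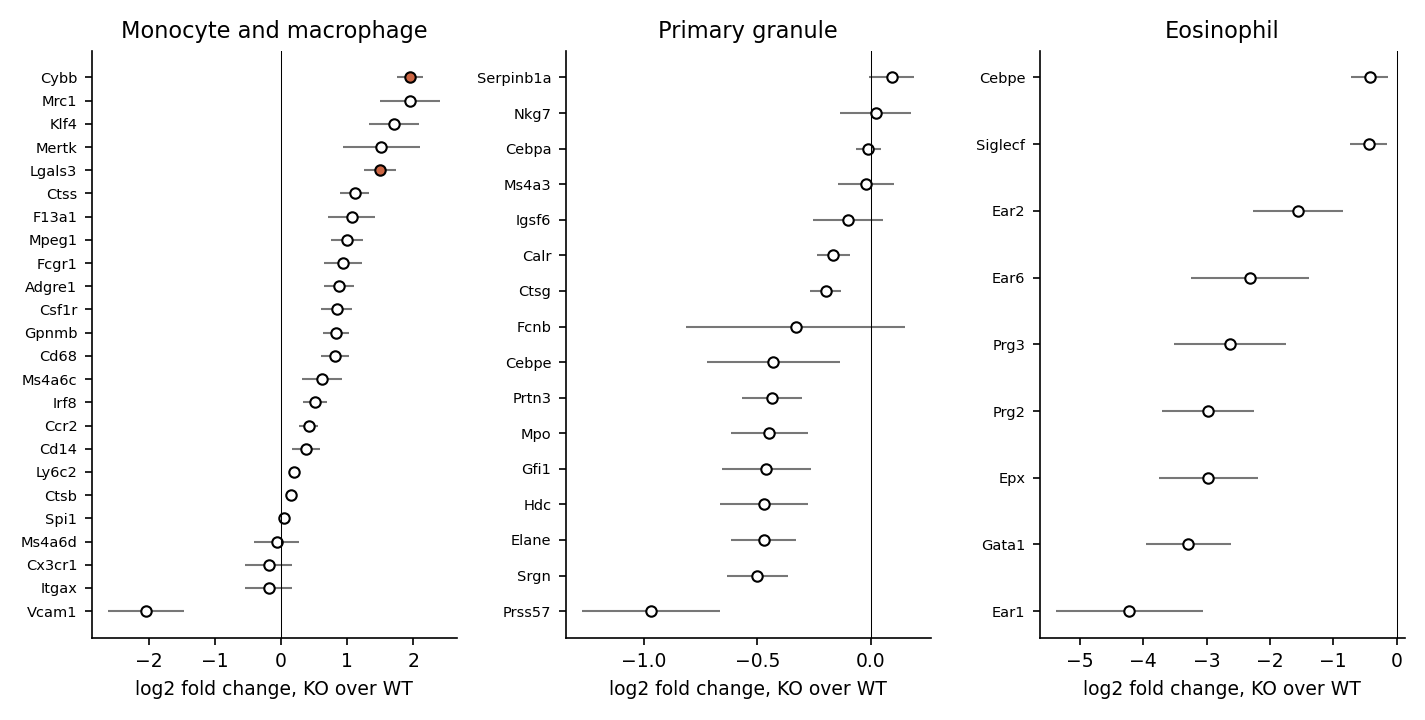
Log2 fold change of KO over WT (points) with its SE (bars) for each measured gene of the monocyte and macrophage (24 genes), primary granule (16) and eosinophil (9) lists; filled points passed an adjusted p of 0.05. Cybb and Lgals3 are the filled points.

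Lipid lists were higher in KO. Of 27 genes of lipid uptake, efflux and storage, 4 rose and none fell, among them Lpl, Lpin1 (log2 fold change 1.02) and the lipid droplet coat gene Plin2 (0.68); 8 were higher and 1 lower adjusted over the list alone. The median was 0.19 (camera adjusted p = 0.000606). Of 25 cholesterol synthesis genes 2 rose, among them Nsdhl (0.78, SE 0.11), 7 were higher over the list alone, and the median was 0.21 (adjusted p = 5.9e-05). Of 29 fatty acid synthesis and elongation genes, only Elovl7, another elongase, rose (0.70, SE 0.13), 9 were higher over the list alone, and the median was 0.17 (adjusted p = 0.0014). The desaturase genes Scd2 and Fads1 had log2 fold changes of 0.44 and 0.45 (adjusted p = 0.0523 and 0.0708, edgeR); both passed without KO replicate 1 (0.55 and 0.57), and Scd2 also without KO replicate 2 (0.32). Of 23 sphingolipid genes, Smpd1, acid sphingomyelinase, rose (1.13, SE 0.12), and 2 were higher over the list alone (median 0.14, camera adjusted p = 0.0204). Smpd1, on the plus strand of chromosome 7, ends at 105558389. Apbb1, named above among the largest rises, lies on the minus strand from 105558483 to 105581653. These genes run towards each other, and whether counting used the strand is not given. Of 27 fatty acid oxidation genes only Plin2, which coats droplets, rose (4 higher over the list alone; median 0.12; adjusted p = 0.0227). With an estimated correlation the adjusted p was 0.547 for each of these lists except fatty acid oxidation, at 0.605. Other lists also hold 4 of the uptake, 2 of the synthesis and elongation, 2 of the oxidation and 1 of the cholesterol genes. Plin2 counts in both the uptake and the oxidation list, so the lipid lists are not independent evidence. The sphingolipid call was lost without WT replicate 2 (adjusted p = 0.0894) or KO replicate 1 (0.13), and its median was 0.079 with no filter on low counts. The fatty acid oxidation call was lost without WT replicate 2 (0.0807) or KO replicate 2 (0.0627); its median was 0.043 without WT replicate 1 and 0.034 without KO replicate 2, and a mean of at least 10 CPM also ended its call (0.12).

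Signalling and glycolysis lists were also higher. Of 21 inflammatory NF-kB genes the chemokine gene Ccl3 (log2 fold change 2.36, SE 0.31) and Tlr2 (0.89, SE 0.15) rose, and 12 were higher over the list alone (median 0.44; camera adjusted p = 2.55e-07). Of 24 glycolysis genes the glucose transporter Slc2a1 (0.55), the lactate transporter Slc16a3 (0.47) and Hif1a (0.41) rose, and 13 were higher over the list alone (median 0.22; adjusted p = 3.86e-06). Of 28 early response genes of MAPK signalling Jun (1.36), Klf6 (1.16) and Dusp5 (0.87) rose; 8 were higher and 1 lower over the list alone (median 0.26; adjusted p = 0.000709). Of 24 chemokine, homing and adhesion genes 3 rose, among them Ccr1 (1.98) and Cd9 (0.98); 8 were higher and 1 lower over the list alone (median 0.19; adjusted p = 0.00109). Of 32 PI3K and AKT genes Pik3ap1 rose (0.34); 8 were higher and 1 lower over the list alone (median 0.093; adjusted p = 0.0184). With an estimated correlation the adjusted p was 0.547 for the first 4 lists and 0.63 for PI3K and AKT. Other lists also hold 3 of the NF-kB, 2 of the glycolysis, 4 of the early response and 5 of the chemokine, homing and adhesion genes. The medians of the NF-kB and early response lists were 0.27 and 0.15 without KO replicate 2, that of PI3K and AKT was 0.16 without KO replicate 1, and the PI3K call was lost without WT replicate 2 (adjusted p = 0.179) or KO replicate 2 (0.0568).

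**Figure D4:**
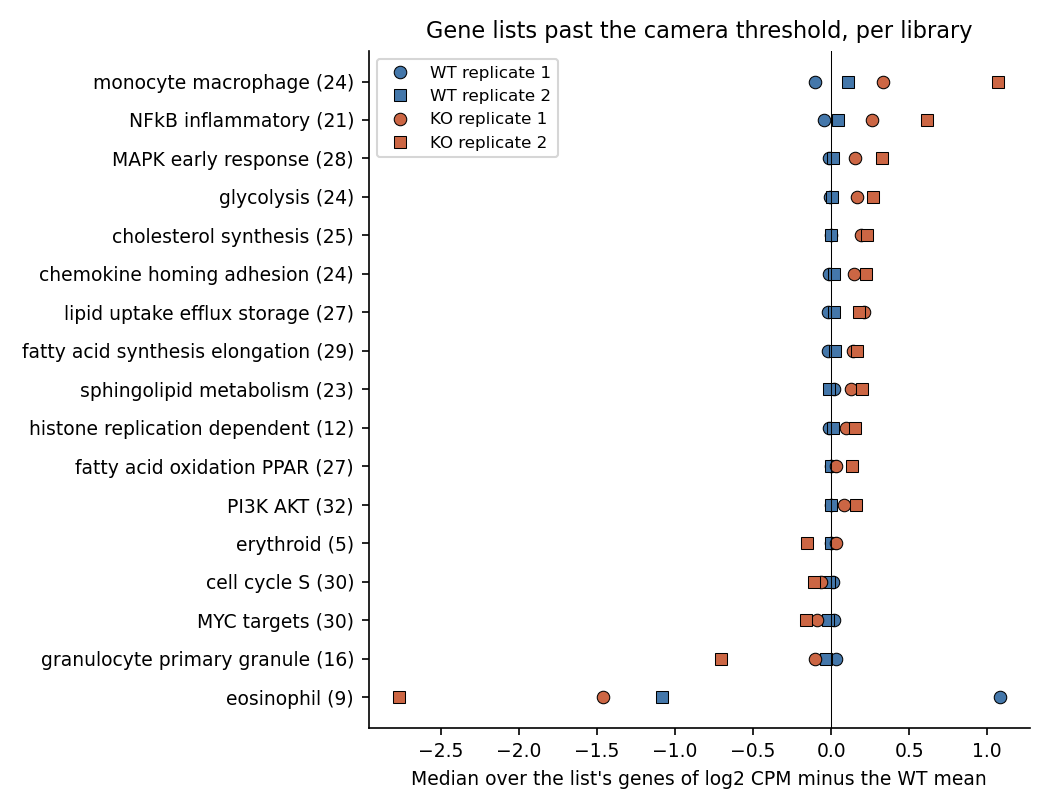
Median over each list's genes of log2 CPM minus the WT mean, per library, for the 17 lists past camera's threshold (number of genes tested in brackets). The monocyte median was 0.33 in KO replicate 1 and 1.07 in KO replicate 2, and the eosinophil medians of the WT libraries lay 1.08 above and below their mean.

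Proliferation and leukaemia lists moved little. Of 30 MYC target genes none passed over all genes and 1 was lower over the list alone (median -0.10; camera adjusted p = 0.00216), and of 30 S phase genes none passed either way (median -0.088; adjusted p = 0.00804). Bub1b, a mitotic checkpoint kinase gene, rose (log2 fold change 0.56, SE 0.053), and it was the only one of 31 G2 and M phase genes to pass (median -0.062, and -0.026 without KO replicate 2; camera adjusted p = 0.311). Of 22 MLL-AF9 target genes 1 fell and 3 were lower over the list alone (median -0.047; adjusted p = 0.163). Hoxa9 and Meis1, which sustain these leukaemias, each had a log2 fold change of -0.30 and missed the threshold (adjusted p = 0.0839 and 0.121, edgeR); both passed without KO replicate 1 (-0.39 and -0.44), and Meis1 was at -0.17 without KO replicate 2. Of 19 stem and progenitor genes Cd93 rose (0.55, SE 0.064; median -0.11, mean 0.10, camera direction up; camera adjusted p = 0.772). With an estimated correlation the MYC and S phase lists had adjusted p = 0.598 and 0.547. Without KO replicate 1 the MYC median was -0.16, and without WT replicate 1 the MLL-AF9 target median was -0.16 (adjusted p = 0.0228); that list also passed with DESeq2 (0.0342), and its median was 0.0046 without WT replicate 2.

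Markers of other cell types and signs of RNA quality were measured alongside. Of 5 erythroid genes Car2 fell (median -0.059, mean -0.99; camera adjusted p = 0.0204, and 0.547 with an estimated correlation). The erythroid call was lost without WT replicate 1, WT replicate 2 or KO replicate 1 (adjusted p = 0.072, 0.0576 and 0.144) and with limma-voom (0.0971), and its median was -0.030 without WT replicate 1, -0.16 without KO replicate 1 and -0.72 without KO replicate 2. With no filter on low counts, which tests more of its genes, it was -1.04. All 12 replication-dependent histone genes had positive values, none passed (median 0.13; camera adjusted p = 0.0293, and 0.547 with an estimated correlation), and leaving out any single library ended that call (adjusted p = 0.0761 and 0.0807 without WT replicate 1 and 2, 0.051 and 0.057 without KO replicate 1 and 2), as did the block (0.0589). Camera called neither mast cell and basophil genes (median -0.17, 12 genes; -0.38 with limma-voom; adjusted p = 0.00801 without KO replicate 2), megakaryocyte genes (-0.17, 10 genes) nor stromal and endothelial genes (0.25, 7 genes; 0.032 without KO replicate 1 and 0.54 without KO replicate 2). Among 4 B cell genes none passed, 3 were lower over the list alone, and the median was -1.41. Thy1 rose (1.41, SE 0.27) among 3 T and NK cell genes (median 1.27), too few in either list to test. Mitochondrially encoded genes took 0.871% and 0.959% of counts in WT and 0.985% and 1.04% in KO (list median 0.019, mean -0.045, camera direction up). Introns held 43.6% to 44.6% of uniquely placed reads in the 4 libraries, and the 10 most abundant genes held 5.27% to 5.99% of counts. With 2 samples against 2, the smallest two-sided p of an exact permutation test of such a value is 1 of 3, so these were not tested.

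The remaining lists were not called by camera. Of 24 mature granulocyte genes Lyz2 rose and Stfa1, a protease inhibitor gene, fell (-2.81, SE 0.53; -4.70 without KO replicate 1), with a list median of 0.27 that became -0.59 without KO replicate 1 and 0.66 without KO replicate 2 (adjusted p = 1.39e-17 in the latter). Of 15 dendritic cell and antigen presentation genes H2-DMb1 fell, and camera's direction was down although the median was 0.090. Single members rose among interferon response genes (Gbp7, 0.58; median 0.20, but 0.36 without KO replicate 1 and 0.11 without KO replicate 2), integrated stress response genes (Stc2, 0.31; median 0.022), p53 and apoptosis genes (Pmaip1, 0.45; median 0.085, but -0.014 without WT replicate 1) and oxidative stress and ferroptosis genes (Hmox1, 1.23, and 0.82 without KO replicate 2; median -0.021, mean 0.042, camera direction up). None passed among unfolded protein response genes (-0.018, mean 0.0040, camera direction down) or nuclear genes of oxidative phosphorylation (-0.066, but -0.11 without WT replicate 2 and -0.030 without WT replicate 1). Of the 33 lists tested, 17 passed an adjusted p of 0.05 by camera, 12 higher and 5 lower. None passed with an estimated correlation (smallest adjusted p = 0.547; 1 list at an unadjusted p under 0.05) or by fry, which asks whether genes move one way on balance (smallest adjusted p = 0.155; 7 lists at an unadjusted p under 0.05).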

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

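The test of intron reads was not among those fixed in advance. Uniquely placed intron reads, a measurement outside the main comparison, also differed between KO and WT. Of 12359 genes tested in intron reads with edgeR, 595 passed an adjusted p of 0.05, and 429 of these were not called in gene counts. Whether introns and gene counts differ in their changes was not tested. Among the 429, 219 were higher in KO and 210 lower. Of 286 genes called in gene counts and tested in introns, 277 had the same sign, with a Pearson r of 0.911 across genes, which are not independent replicates.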

How the results depend on the processing

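Elovl6 kept its direction and call in all 13 alternatives, at log2 fold changes from -6.16 to -5.27, and no called gene named here turned its sign. The count of called genes stayed within 1.5 times of 329 with RLE (304) or upper quartile scaling (395), DESeq2 (484), limma-voom (222), abundant genes left out (410) and uniquely placed exon reads (387, chosen after seeing the data). It was 1677 with no filter on low counts, 112 with a mean of at least 10 CPM, 850 at an adjusted p under 0.1 and 169 with an absolute log2 fold change of at least 1. Leaving out 1 library gave from 14 to 1449, with fewer samples and the lone sample assumed to vary like the other group; why the count rose without KO replicate 1 was not tested. With the replicate number as a block it was 875, holding all 329; same-numbered samples correlated at 0.155 over 2 pairs, too few to show that they share more than a number. The 17 list calls became 0 with an estimated correlation and 0 by fry; the cause was not tested. No called list turned, but 8 uncalled lists did in camera's direction. Leaving out single libraries, the medians ran from -0.13 (without KO replicate 1) to 0.17 (without WT replicate 2) for stem and progenitor genes, which also turned without WT replicate 1 (-0.094), and from -0.59 (KO replicate 1, turned) to 0.66 (KO replicate 2) for mature granulocyte genes. Dendritic genes ran from -0.21 (KO replicate 2) to 0.20 (KO replicate 1, turned), and also turned without WT replicate 2 (0.066), with limma-voom (0.13) and with the block (0.12). Megakaryocyte genes ran from -0.30 (KO replicate 1, turned) to -0.028 (KO replicate 2), and turned with the block (-0.18). Without WT replicate 1 turned unfolded protein response genes (-0.015; range -0.060 to -0.015) and mitochondrially encoded genes (-0.036; range -0.036 to 0.18). Integrated stress response genes turned without KO replicate 1 (-0.0023; range -0.0093 to 0.017) and oxidative stress genes without WT replicate 2 (-0.072; range -0.072 to 0.026). Of genes not called, Nfe2 (0.035; range -0.16 to 0.035) and Ighm (-0.0017; range -0.0017 to 0.27) turned without KO replicate 2. The cause was not tested for any of these. The pseudocount alternative was not run because the values are counts, nor was crossed pairing, because same-numbered samples correlated positively. Depth limits what can be said of genes with 3 or fewer counts in a group.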

Other observations

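The tests of strain differences elsewhere in the genome, by neighbours and by windows, and those of uniquely placed counts, taken apart by gene, of cell type shares and of mixed cells were chosen only after the results they bear on were seen. Called genes were spread over the genome but gathered in 3 of 275 windows of 10 Mb. On chromosome 7, from 110000001 to 120000000, 9 of 47 tested genes were called, 7 of them lower, including Pde3b, which degrades cyclic nucleotides (log2 fold change -2.44, SE 0.20), and Rps15a (-0.77, SE 0.065). On chromosome 2, over the same interval, 8 of 52 were called, including the protease inhibitor gene Spint1 (-2.49, SE 0.27). On chromosome 17, from 30000001 to 40000000, 14 of 155 were called, among them the mismatch repair relative Msh5 (2.45, SE 0.16) and the class I genes H2-Q4 (1.45) and H2-Q6 (2.10). These genes were picked from the windows after their values were seen. Of the 14 called on chromosome 17, 11 were higher and 3 lower. Genes named earlier also lie in these windows: Rassf10 on chromosome 7, Bub1b on chromosome 2, and H2-DMb1 and H2-Q10 on chromosome 17. The 3 windows held 31 called genes, with adjusted p of 0.00141, 0.0107 and 0.0107 (hypergeometric), and 298 lay outside.

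The genes with the largest changes sat at near-absent levels in one genotype, and Eif3j2 rose while its copy Eif3j1 fell. A segment of another strain carried along with the knocked-out allele, acting on its own genes, is argued against for these changes. Of the 23 genes of largest change besides Elovl6, 0 lie within 10 Mb of Elovl6. That does not decide whether such a segment is there. Of the 66 other tested genes within 10 Mb, 4 were called, against 329 of 11738 in all. Also argued against, for the counts of these 23 genes only, is the division of multi-mapping reads. Of the 23 genes 19 had counts made of uniquely placed reads alone, which hold no divided reads; this fixed the ratio of the median absolute change in such reads to that in gene counts over all 23, at 0.999, which decides nothing. In the other 4 genes that ratio was 1.01, and 0.881 in the lowest of them. Uniquely placed reads made up 51.8% (Xlr4b) to 92.3% (Mid1) of their counts, which partly fixes that ratio too. For Eif3j2 and AL607105.1 they were 4.25% and 21.7% of exon reads, so most exon reads lie outside those counts. Eif3j1 was not among the 23, and whether reads of a gene were placed on its copy was not tested. Strain differences elsewhere between KO and WT donors stay open. By annotated chromosome and start, 0 of the 23 lay within 5 Mb of another. X and Y were treated as separate, so Mid1 (X) and Erdr1 (Y) count as apart, and whether they share a region was not examined. Random draws gave a median of 2 and a 5th percentile of 0, so that test decides nothing. That the number must fall below the draws to exclude such differences was required only after its value was seen. Counted over all called genes, the fullest window, on chromosome 17, held 14 against a 95th percentile of 10 in shuffles (median 8). Such segments could give this, though the families of similar genes on chromosome 17 could give it too. Those families do not bear on the windows on chromosomes 7 and 2, where 9 of 47 and 8 of 52 tested genes were called. Of the 23, Rassf10 and H2-Q10 lie in the windows on chromosomes 7 and 17. Loss of Elovl6 also remains open. For these 23 genes, the other called genes and the lists, it cannot be told apart from strain differences, since both would follow the genotype.

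The monocyte and macrophage list was higher and the primary granule list lower in KO. A change after transcription only is argued against, since the monocyte median in intron reads was 0.561. A lower share of the main cell type, with the other types kept in proportion, is argued against as the whole cause. It would raise the markers of every other type alike, but the lists of 7 other types moved apart. Of their medians 5 lay below 0 and 2 above. The 5 include 4 of 4 in a subset picked after values were seen (mast cell, eosinophil, erythroid and megakaryocyte). The 3 T and NK cell genes had positive values (median 1.27), as such a share would give, though only Thy1 passed. Their library medians were 0.973 and 1.55 in KO and 0.226 and -0.226 in WT, and the stromal median was 0.25. Megakaryocyte, erythroid and stromal genes went both ways, so the argument rests on 2 lists: 10 of 12 mast cell and basophil genes were lower (library medians -0.183 and -0.176 in KO, 0.0448 and -0.0448 in WT), as were 9 of 9 eosinophil genes (-1.46 and -2.77 in KO, 1.08 and -1.08 in WT), while monocyte medians were 0.33 and 1.07 in KO, and -0.106 and 0.106 in WT. That at least 2 lists must part in this way was settled after these values were seen, and camera did not call the mast cell list. A larger share of monocytes, also at the cost of the main type, or a change within them, stays open. That the second KO library set most of the shift is not excluded: without it the monocyte median was 0.33 against 0.83, under the bound set before the result was seen. Camera still called the list without it (adjusted p = 1.44e-08; at most 5.62e-05 over 13 alternatives, but 0.547 with an estimated correlation and 0.312 with fry), and the list medians of both KO libraries lay above those of both WT libraries. The size of the shift may therefore depend on that sample. Elovl6 genotype remains an open explanation of the rest, as do strain differences that would follow it.

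Intron reads of Elovl6 stayed far above the level of its exon reads in KO. Wild-type cells mixed into the KO libraries are argued against as the source of most of these intron reads. They would bring both kinds of read in the same ratio. The share of intron reads kept was at least 22.1 times that of exon reads. Whether such cells gave the 17 and 34 exon reads left in KO cannot be told from this ratio. An allele that is still transcribed but yields little spliced RNA may account for the intron reads. No test here addressed that hypothesis, and the overlapping predicted gene was not separated from it.

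Eif2s3y, a gene of the Y chromosome, had 328 and 32 counts in the WT libraries and 413 and 576 in KO, while Uty and Ddx3y differed by log2 fold changes of -0.32 and -0.27 between genotypes. Prg2 had 1537 and 520 counts in the 2 WT libraries, and Epx had 1484 and 402. The RNA gene Gm26917, not named by the rule and singled out after its counts were seen, held 1.98% to 2.67% of gene counts. In intron reads the median of the glycolysis list was -0.037 against 0.20 for the same genes in gene counts, and that of the MAPK early response list was -0.090 against 0.14.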
